A study of Caenorhabditis elegans with 2 samples.

How the data were processed

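The data come from chromatin immunoprecipitation and sequencing of eGFP-tagged MEF-2 in whole L1 larvae of C. elegans strain OP301, in 2 biological replicates that form 1 group. Per the labels, the size range of the libraries was 150 to 350 bp, the antibody is recorded under the name mef-2, and the assemblies are ce11 and ce10. For each of the 2 builds, 4 deposited peak lists were used: the relaxed list of each replicate, the relaxed list of the pooled replicates, and the list thresholded by the irreproducible discovery rate (IDR), a measure of the rank agreement between replicates. Per the deposited file records, each relaxed list was called against a control, and the thresholded list was made from the pooled list and both replicate lists. The aligner, the peak caller, their versions and the IDR limit are not given in the sources used here. Read counts, signal tracks and a control library were not used here, so depth per sample is unknown and no floor that needs it is given.

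Each peak has a signal value from the authors' caller, used here only to rank, describe, filter or compare peaks within a list, and by rank between replicates, since its scale is not stated. The authors' lists also give a −log10 q-value per peak, which was the same for all 832 thresholded peaks and was not used for tests. The column for the position of the point source, also deposited, gave the site of each peak; nearly all peaks of a list had its median width, and their point sources lay at the middle. On ce11 the thresholded list was made up of exactly the 832 strongest entries of the 28182 in the pooled list (828 of 28223 on ce10), so the limit acts as a minimum signal value of 27.4 in the pooled data. A site strong in the pooled data but weak in one replicate can therefore be listed.

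Genes, exons and biotypes came from Ensembl release 115, and sequence from the matching reference genome WBcel235, which is ce11. No coordinates were converted between builds. The ce10 lists were used only for list agreement and chromosome counts, with the largest peak end on each chromosome standing in for its length.

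The choice of groups, tests, windows, gene lists, elements, naming rule and most alternatives was made before the data were examined. Replicates were compared by the share of the 832 strongest peaks of each that overlapped by at least 1 bp, against 1000 circular shifts of one list along each chromosome. Chromosome counts were tested with an exact binomial test against the share of nuclear length. A peak was placed at a 5' end when its point source lay from 1000 bp upstream to 200 bp downstream of the outermost annotated 5' end of a protein-coding gene, and these shares were set against circular shifts. Gene lists of at least 5 matched members were compared with all other nuclear protein-coding genes by Fisher's exact test, and so were 6 classes of non-coding genes with all protein-coding genes. Odds ratios are conditional maximum likelihood estimates. The 25 lists cover muscle, the neuromuscular junction, MEF-2 and its described regulators and partners, neurons, other tissues, transcription factor families and general cell functions. The names tag-163, mir-1 and cup-9 matched no nuclear protein-coding gene and were left out.

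Elements were searched on both strands within 100 bp of the point source and in 2 flanking windows of the same width centred 500 bp away. The difference of shares was tested by 100000 random sign flips over peaks. All 6-mers, pooled with their reverse complements, were compared between each point-source window and 1 of its flanks, picked at random, by an exact McNemar test. Shuffled windows kept their dinucleotide counts, with 50 copies per window. Medians of the signal value were compared with 100000 permutations. Around mef-2, peaks within 20 kb of the gene were counted against all nuclear windows of that size, those that overlap mef-2 included. Families of tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The smallest p that the shifts can give is 0.001, and the smallest from the permutations is 1e-05.

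Named genes follow a rule fixed beforehand. It takes the 25 strongest thresholded peaks with the nearest protein-coding 5' end within 2 kb; up to 4 members with the highest signal value from each list past the threshold and from the muscle, neuromuscular and MEF-2 lists; and mef-2. Genes outside the rule are said to be so where they appear.

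Alternatives were another overlap rule, list size, build, 5' window, background, element, element width, threshold (the 416 strongest peaks) and the lists of single replicates, in which the rank of each named peak was also taken. Without replicate 1 stands for the 832 strongest peaks of replicate 2, and the reverse. Added after the data had been seen were nuclear peaks alone, the lists and chromosome counts without peaks near mef-2, the strict element on nuclear peaks, flanks with each window set against its shuffled copies, and some single-replicate versions. After the first output, an odds ratio with 0.5 added to each count was replaced, since it gave a direction to lists with 0 peaks; the planned comparison of lists with circular shifts now uses the ratio of shares in both tails. The number of shuffled copies was raised from 10 to 50 after the first values had been seen.

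The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. A planted share of 60.7% of 832 peaks at 5' ends came back as 62.1%, and 50% shared peaks as 50.1%. A raised gene list was called in 96% of 50 trials, and unchanged lists in 0.25% of 1200. An element planted at 9.76 percentage points over flanks came back as 9.92, and a rise of 9 points over shuffled copies in 400 peaks as 8.64. A planted difference of medians of 20 came back as 19.1 and an X chromosome ratio of 1.38 as 1.52. With random peaks, the 5' end test called 4% and the element test 6% of 100 trials.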

Results

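MEF-2 is the C. elegans member of the MEF2 family of MADS-box transcription factors, whose relatives bind the A/T-rich element YTAWWWWTAR (Y is C or T, W is A or T, R is A or G). Its positions on chromatin were mapped by chromatin immunoprecipitation and sequencing in whole L1 larvae, the first larval stage, of strain OP301. This strain carries the integrated transgene wgIs301, from which MEF-2 is made as a fusion with eGFP. The data form 1 group of 2 biological replicates, with no treatment and no other stage to compare. The peak lists give no read counts, so the depth of each library is unknown, and a control library was not analysed here. The authors' relaxed lists, which hold peaks together with background, contained 30000 intervals in replicate 1 and 16385 in replicate 2, with median widths of 344 and 284 bp. Their thresholded list, made from both replicates, held 832 peaks, 806 on the nuclear chromosomes and 26 on mitochondrial DNA. Coordinates are on ce11. Peaks and genes are not replicates, so the p-values describe this peak set, and intervals cover counting error only.

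The replicates placed many of their strongest peaks at the same sites. Of the 832 strongest peaks of replicate 1, 50.96% overlapped one of the 832 strongest of replicate 2 by at least 1 bp, and 50.7% of those of replicate 2 overlapped one of replicate 1. Permutation of one list by 1000 circular shifts along each chromosome gave a mean of 0.526% and at most 1.68% (one-sided p = 0.001, the smallest these shifts can give). The strongest site of replicate 2 lay in an intron of mef-2, and the upstream regions of the ribosomal protein genes rpl-3 and rpl-15 held its peaks of rank 2 and 6. The same sites ranked 8, 32 and 36 in replicate 1, where 30 mitochondrial peaks were among the 832 strongest.

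Of the 806 nuclear thresholded peaks, 784 overlapped an interval in both relaxed lists, 21 in replicate 1 alone and 1 in replicate 2 alone. Among the peaks found in replicate 1 alone were those upstream of tax-6, the catalytic subunit of calcineurin, and of unc-11, a clathrin adaptor. Across the 784 peaks, Spearman's rho between the authors' signal values in the replicates was 0.176, and 0.169 without the 2 peaks strongest in replicate 1. These peaks were selected on the pooled signal, which by itself lowers rho, so it does not measure how far peak strength was shared. Of the nuclear peaks, 416 were among the 832 strongest of both replicates. Of the other list genes named in the text, atp-2, unc-76, ric-3 and ipgm-1 had peaks among the 832 strongest of replicate 1 that ranked 1801, 3569, 2601 and 1991 in replicate 2, beside the peak upstream of mef-2 described next. In the other direction, the peaks at egl-21, col-38 and hlh-30 ranked 1299, 1713 and 1169 in replicate 1 but 78, 181 and 657 in replicate 2, and that of srh-16 ranked 951 and 1067. Of these genes, ipgm-1, col-38 and hlh-30 fall outside the naming rule and were named after their values were seen.

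**Figure D1:**
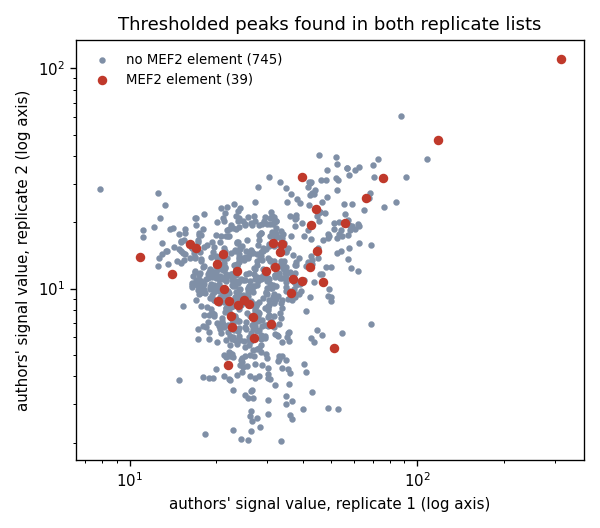
Each point is a thresholded peak that overlapped an interval in both relaxed lists (784 peaks), placed by the authors' signal value in replicate 1 and in replicate 2 on log axes, with peaks holding a MEF2 element in red. Spearman's rho across these peaks, which were selected on the pooled signal, is 0.176, and the peak at the upper right is the one in the mef-2 intron.

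The strongest of all 832 peaks lay inside mef-2 itself. It spanned chromosome I from 9097623 to 9098049, in the intron between the exon ending at 9096065 and the exon starting at 9098443, 1877 bp downstream of the annotated 5' end, with a signal value of 428 against a median of 37.2 for the list. Within 100 bp of its point source it held 1 MEF2 element, CTATTTTTAG. A further peak with a signal value of 71.0 lay 219 bp upstream of the mef-2 5' end, from 9095568 to 9095907, and held no element; it ranked 40 in replicate 1 but 1344 in replicate 2, outside the 832 strongest there. The gene (WBGene00003182) runs from 9095957 to 9100862 on the forward strand.

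Peaks were crowded over the whole neighbourhood of mef-2. From 20 kb before the gene to 20 kb after it, 9 thresholded peaks were found, where 2229 nuclear windows of that size held a mean of 0.362 and at most 8. The pooled relaxed list had 48 intervals there against a mean of 12.6 and at most 45, replicate 1 had 42 against a mean of 13.4, and replicate 2 had 36 against 7.34. The windows were not cleared of mef-2, and a window over most of this stretch holds 8 thresholded peaks and 45 pooled intervals. The maxima therefore cannot be read as those of another region. Of the 9 thresholded peaks, 1 held a MEF2 element, the peak in the intron. In bins of 5 kb, the pooled list had a mean of 5.25 intervals within 20 kb of the gene (8 bins) and 1.64 beyond 40 kb (14 bins, out to 80 kb), beside 1.40 over the nuclear genome. Replicate 1 had means of 4.63, 1.57 and 1.49 in the same order, and replicate 2 had 4.13, 1.57 and 0.817. Beyond 40 kb the mean of replicate 2 was thus still above its genome mean, but only through the bins after the gene. Before the gene each bin beyond 40 kb held 0 or 1 replicate 2 intervals, and after it 1 to 5. The distances of these bins were chosen after the counts had been seen.

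**Figure D2:**
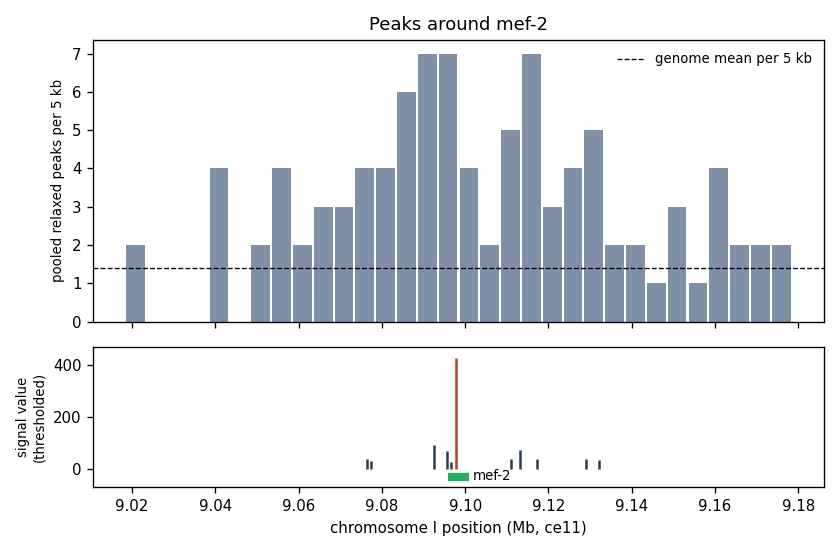
The upper panel gives the number of pooled relaxed intervals per 5 kb along chromosome I around mef-2, with the genome mean of 1.40 as a dashed line. The lower panel gives the authors' signal value of each thresholded peak within 40 kb of the gene, in red where it holds a MEF2 element. The mef-2 gene is a green bar, and the thresholded peak at eef-2, farther from the gene, is not drawn. The tallest line is the intronic peak at 428, and all bins within 20 kb of the gene lie above the genome mean.

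Among the 25 strongest peaks, 14 were mitochondrial and 11 nuclear. After mef-2 came peaks 205 bp upstream of F53C3.6 (chromosome II, 3897827 to 3898032, signal value 164), 279 bp upstream of rpl-3 (chromosome III, 3867499 to 3867671, 149) and 170 bp upstream of cdc-48.1, a AAA ATPase that extracts ubiquitylated proteins (chromosome II, 10563488 to 10563658, 147). Peaks also stood 347 bp upstream of rpl-15 (chromosome IV, 654866 to 654987, 111.9), 69 bp upstream of iff-2, which encodes the translation factor eIF5A (chromosome II, 8561266 to 8561605, 106), and 177 bp upstream of Y17G9B.5, a peak that also lies 285 bp upstream of rpl-20 (chromosome IV, 4750011 to 4750119, 101.1). Peaks in introns were found in Y111B2A.12 (chromosome III, 12612540 to 12612879, 123.2), ndnf-1 (chromosome IV, 3026016 to 3026157, 108) and W06H8.6 (chromosome V, 6224555 to 6224894, 102). The last of the 11 was an intergenic peak on chromosome X (16726881 to 16727027, 103.7), 2561 bp upstream of hda-4, a class IIa histone deacetylase; this lies beyond the 2 kb within which a gene was to be named, as do the 5' ends of Y111B2A.12, ndnf-1 and W06H8.6, and these 4 genes are named here after their values were seen. Of these 11 peaks, those at mef-2, F53C3.6 and ndnf-1 held a MEF2 element.

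More than a chance share of the peaks lay just upstream of protein-coding genes. Of the 832 point sources, 458 (55.05%, 95% Wilson interval 51.7 to 58.4) were within 1000 bp upstream and 200 bp downstream of a gene's 5' end, against 22.7% (SD 1.42) over 1000 circular shifts (one-sided permutation p = 0.001, the smallest possible). On nuclear chromosomes alone the share was 53.8% against 20.9%. Outside these windows, coding exons held only 5 peaks, 0.601% against 19.7% in the shifts. Introns there held 159 (19.1% against 29.3%), and 3' untranslated regions with the 500 bp beyond them 29 (3.49% against 6.64%). Each of these 3 shares was lower than in the shifts (permutation p = 0.001 in the lower tail). Each peak was counted in 1 class only, the 5' end window first, so the higher share at 5' ends lowers the other shares by itself. Peaks in coding sequence within a 5' end window, several of the strongest mitochondrial peaks among them, therefore count at 5' ends. For introns and 3' regions, at 0.653 and 0.525 times the share in the shifts, the test cannot separate depletion from that effect. Coding exons fell much further, to 0.0306 times. Intergenic sequence outside these windows held 171 peaks, 20.6% against 20.9%, with a lower-tail permutation p of 0.423. The higher share at 5' ends bears on this class too, so a share near that of the shifts does not show that it was unchanged. The 5' untranslated regions beyond the window held 10, 1.202% against 0.795%, with an upper-tail permutation p of 0.133.

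Among the chromosomes, V carried fewer nuclear peaks than its length gives, 109 of 806 at 0.648 times the expected share (exact binomial test, adjusted p = 5.25e-07 over 6 chromosomes). Chromosome I had 148 peaks at 1.22 times (exact adjusted p = 0.0309), but without the 9 peaks near mef-2, a set chosen after the data had been seen, the ratio was 1.16 and did not pass (exact adjusted p = 0.0894). Chromosome III had 133 peaks at 1.2 times (exact adjusted p = 0.0553), and passed with the 416 strongest peaks, the ce10 list, either replicate alone and gene 5' ends in place of length (1.2 to 1.40 times, exact adjusted p from 0.00151 to 0.0478). X had 165 peaks at 1.16 times (exact adjusted p = 0.0630), II had 107 at 0.871 times (0.154) and IV had 144 at 1.02 times (0.745). Against the share of gene 5' ends in place of length, 5 chromosomes passed the threshold, X among them at 1.497 times (exact adjusted p = 3.34e-07).

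Genes of protein synthesis, protein folding, splicing and respiration carried peaks at their 5' ends far more often than other genes. A peak was found at the 5' end of 585 of 19973 nuclear protein-coding genes (2.93%). Taking the strongest peak of each gene, these were 431 distinct peaks, of which 143 served more than 1 gene. Of 25 gene lists, 7 had a higher and 1 a lower share than all other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p over the 25 lists). Cytosolic ribosomal proteins led with 32 of 82 genes (39.0%, 95% Wilson interval 29.2 to 49.8, odds ratio 22.4, exact adjusted p = 1.41e-26). The signal value was 149 at rpl-3, 111.9 at rpl-15, 101.1 at rpl-20 and 99.5 at rpl-35. Of 42 translation factors, 9 had a peak (21.4%, odds ratio 9.16, exact adjusted p = 1.17e-05), with 106 at iff-2, 84.9 at eef-1A.2, 42.4 at eef-2 and 41.4 at eef-1A.1, the last 3 being elongation factors.

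Chaperones and heat shock proteins had a peak at 13 of 63 genes (20.6%, odds ratio 8.79, exact adjusted p = 2.33e-07). The highest were at cct-8 (70.4) and cct-1 (58.6), subunits of the cytosolic chaperonin, then at hsp-60 (58.2), the mitochondrial chaperonin, and hsp-1 (52.2), an HSP70. Spliceosome and RNA processing factors had 12 of 58 (20.7%, odds ratio 8.80, exact adjusted p = 5.81e-07), with prp-19 at 52.2, prp-8, a core protein of the U5 particle, at 47.01, prp-40 at 44.7 and the SR protein gene rsp-6 at 37.96. In oxidative phosphorylation, 13 of 73 genes carried a peak (17.8%, odds ratio 7.32, exact adjusted p = 8.81e-07): cox-5A at 87.3, cytochrome c1 gene cyc-1 at 51.5, nduc-2 at 49.5 and atp-2, the beta subunit of ATP synthase, at 48.2. Of the genes named here from these 5 lists, cct-1 and rsp-6 held a MEF2 element at the peak. Among genes with a pooled relaxed peak at the 5' end, the odds ratios were 8.87 for ribosomal proteins, 5.82 for translation factors, 5.54 for chaperones, 5.70 for spliceosome factors and 3.41 for oxidative phosphorylation, all past the threshold. Without replicate 2 the ribosomal odds ratio was 14.7, and with each peak given to the nearest gene only it was 14.4, and 4.87 for chaperones.

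Genes of the MEF-2 pathway and neuronal genes showed smaller counts. Of 10 genes for MEF-2 and its described regulators and partners, 3 had a peak (30%, 95% Wilson interval 10.8 to 60.3, odds ratio 14.3, exact adjusted p = 0.00919). They were mef-2 (71.0), kin-29, a salt-inducible kinase that acts on chemoreceptor expression through MEF-2 and HDA-4 (chromosome X, 2852581 to 2852920, 313 bp upstream, 32.4), and tax-6 (chromosome IV, 10502402 to 10502741, 972 bp upstream, 28.4). Of 30 pan-neuronal genes, 4 had a peak (13.3%, odds ratio 5.13, exact adjusted p = 0.0341): the Ras exchange factor gene rgef-1 (50.4), the neuropeptide processing gene egl-21 (39.5), the axon outgrowth gene unc-76 (38.1) and unc-11 (30.2). Neither call held against circular shifts of the peaks (permutation, adjusted p = 0.450 and 0.250). Without the peaks near mef-2, the exact adjusted p of the MEF-2 list was 0.102.

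Chemoreceptor genes, most of which act in few sensory neurons, were nearly free of peaks. Only sri-5 (35.2) and srh-16 (27.9) of 1302 carried one (0.154%, odds ratio 0.0477, exact adjusted p = 7.40e-14), and among genes with a pooled relaxed peak the odds ratio was 0.0868. No peak was found at the 5' end of any of 49 body wall muscle genes for the sarcomere and its attachment (upper Wilson limit 7.27%; exact adjusted p = 0.675), nor at any of 10 pharyngeal muscle genes. Of 29 genes of the neuromuscular junction, ric-3, a chaperone of acetylcholine receptors, had a peak (30.4; exact adjusted p = 0.783). The number of genes sets wide limits here, so a share close to the genome's 2.93% was not excluded for these muscle lists.

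Markers of other tissues and the remaining lists did not differ detectably from other genes (Fisher's exact adjusted p from 0.189 to 1). Intestine (0 of 34), hypodermis and seam (0 of 30), germline (0 of 34), glia (0 of 14) and coelomocytes (0 of 6) held no peak, and the excretory canal list held 1 of 13, at vha-8. Cuticle collagens had 1 of 176 (col-38), neuropeptides 1 of 140 (ins-39), homeobox factors 1 of 93 (ceh-38), core histones 1 of 72 (his-37) and glycolysis 1 of 19 (ipgm-1). Nuclear hormone receptors had 4 of 274 (nhr-1, nhr-48, nhr-49 and nhr-142), helix-loop-helix factors 2 of 40 (hlh-11 and hlh-30) and the proteasome 2 of 33 (rpn-3 and rpn-11). The genes of these other lists were named after their values were seen.

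**Figure D3:**
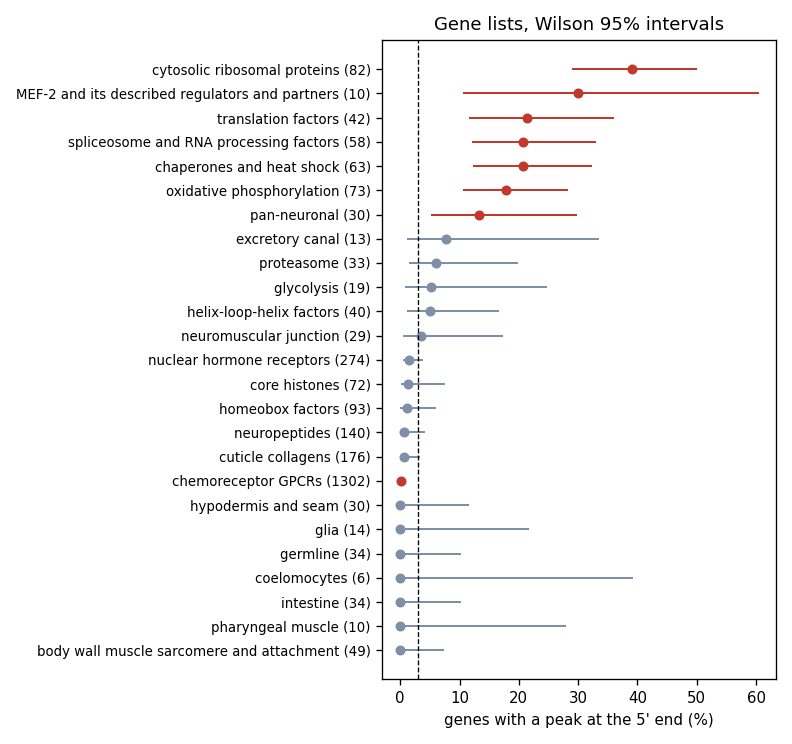
Points give the percent of each list's genes with a thresholded peak at the 5' end, with the number of genes in brackets, and lines the 95% Wilson intervals; red marks the 8 lists past an adjusted p of 0.05, and the dashed line the 2.93% of all genes. Ribosomal proteins stand farthest to the right at 39.0%, and chemoreceptor genes lie at 0.154%.

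Small nucleolar RNA genes also carried peaks more often than protein-coding genes. Of 346 snoRNA genes, 34 had one at the 5' end (9.83% against 2.93%, odds ratio 3.61, Fisher's exact test, adjusted p = 1.28e-08 over 6 classes). Of those 34, 15 lie inside a protein-coding gene and 22 share their peak with a protein-coding 5' end, so the class is not separate from protein-coding 5' ends. Transfer RNA genes had 27 of 612 (4.41%, exact adjusted p = 0.116), small nuclear RNA genes 8 of 129 (6.202%, 0.116), microRNA genes 11 of 261 (4.21%, 0.298), lincRNA genes 7 of 194 (3.61%, 0.623) and ribosomal RNA genes 0 of 20. Transfer RNA and small nuclear RNA genes passed the threshold with a window of 500 bp upstream to 100 bp downstream (exact adjusted p = 0.0375 and 0.0274). Transfer RNA genes also passed in the 832 strongest peaks of either replicate (exact adjusted p = 0.0237 in replicate 1 and 0.0119 in replicate 2), and small nuclear RNA genes in those of replicate 2 (0.0119) but not replicate 1 (0.248). In the thresholded list, several neighbouring transfer RNA genes share a peak, and the test counts such genes as if they were independent.

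The MEF2 element was rare at the peaks, and whether it was more frequent there than nearby depended on the element's form and on the background. Of 831 peaks with complete windows, 48 (5.78%) held it within 100 bp of the point source, against 7.46% in windows centred 500 bp to each side, a difference of -1.68 percentage points (SE 1.05, sign-flip permutation p = 0.122, two-sided). The strict form CTAWWWWTAG was found at 1.56% of point sources and 0.481% of flanks, a difference of 1.08 points (SE 0.449, permutation p = 0.0209), and the element exceeded copies of the same windows shuffled with their dinucleotides kept, 5.78% against 2.19%, by 3.59 points (SE 0.792, p = 1e-05, the smallest possible). With each window set against its own shuffled copies, point sources exceeded flanks by 2.76 points (SE 1.04, permutation p = 0.00794), a comparison chosen after the data had been seen. The looser form TAWWWWTA went the other way, at 15.04% of point sources and 24.6% of flanks (-9.57 points, SE 1.57, permutation p = 1e-05).

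In the plain comparison with flanks, several other elements showed larger differences. GAGAG was present at 67.7% of point sources and 23.6% of flanks (difference 44.1 points, SE 1.90, permutation p = 3e-05 after adjustment over 9 elements). It also exceeded shuffled copies by 22.5 points (SE 1.34). CACGTG, the E-box of Myc-like helix-loop-helix factors, stood at 9.99% against 3.49% (6.50 points, SE 1.13, adjusted permutation p = 3e-05), and CCGCCC at 9.27% against 3.43% (5.84 points, SE 1.07, adjusted permutation p = 3e-05). The general E-box CANNTG differed by 8.42 points (SE 2.09, adjusted permutation p = 0.000225) and CAGCTG by 4.27 points (SE 1.09, adjusted permutation p = 0.000234), the latter not past the threshold among the 416 strongest peaks (2.77 points, adjusted p = 0.105). With each window set against its own shuffled copies, again chosen later, the excess over flanks fell to 22.01 points for GAGAG, 5.26 for CANNTG, 4.52 for CACGTG, 3.81 for CCGCCC and 2.34 for CAGCTG (adjusted permutation p = 0.0447 for the last, lower for the others). The GATA element WGATAR was less frequent than in flanks, 31.6% against 37.0% (-5.35 points, SE 1.99, adjusted permutation p = 0.0119), but not less frequent than in shuffled copies, which it exceeded by 2.47 points (SE 1.56, adjusted p = 0.131). TGACTCA (0.481 points, adjusted permutation p = 0.463) and the altered control YTAWWWWGCR (-1.26 points, SE 0.627, adjusted p = 0.0714) did not pass, but the control passed on nuclear peaks (-1.36 points, adjusted p = 0.0497), and TGACTCA was less frequent than in shuffled copies (-1.08 points, adjusted p = 0.0389).

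**Figure D4:**
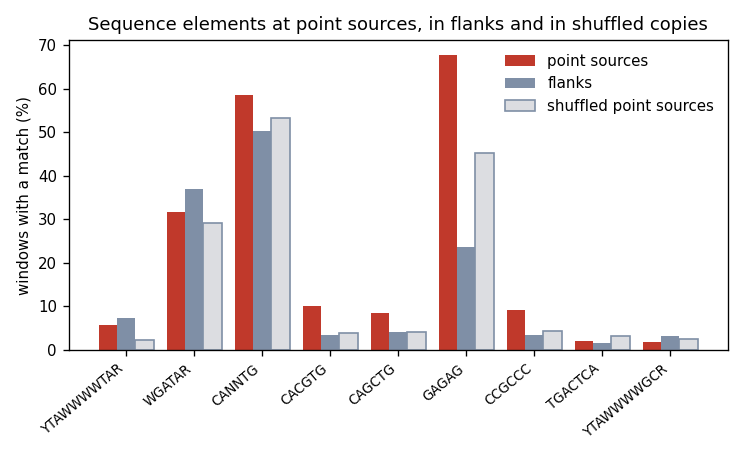
Bars give the percent of windows of 201 bp with at least 1 match to each element, at 831 point sources (red), in the flanks of the same peaks (blue-grey) and in shuffled copies of the point-source windows (light). GAGAG reaches 67.7% at point sources against 23.6% in flanks, and the MEF2 element YTAWWWWTAR stands at 5.78%, 7.46% and 2.19%.

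Peaks with a MEF2 element were stronger within the thresholded list. Their median signal value was 44.6 (n = 48) against 36.9 for the 783 without it, a difference of 7.63 (permutation p = 0.00102, two-sided). Mitochondrial peaks contributed to this: on nuclear chromosomes alone the medians were 39.5 and 36.5 (difference 2.98, permutation p = 0.160). With the element sought within 50 bp of the point source, mitochondrial peaks included, the difference was 16.9 (permutation p = 0.0003). Among the 832 strongest peaks of replicate 2 the difference was 0.610 (permutation p = 0.528). Peaks at gene 5' ends had a median of 37.3 (n = 458) and the other peaks 37.1 (n = 374), a difference of 0.107 (permutation p = 0.923).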

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

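The tests in this part were chosen after the mitochondrial peaks had been seen. Mitochondrial DNA lies outside the gene lists and the chromosome counts, though its peaks entered the 5' end share and the element and signal tests. Replicate 1's relaxed list held 32 mitochondrial peaks, 30 of them among its 832 strongest, and the thresholded list held 26, of which 14 are among its 25 strongest peaks.

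A candidate explanation is a difference between the replicates in how much mitochondrial DNA their reads or lists retain, with no bound site. Intervals of replicate 1 covered 64.5% of the 13794 bp of mitochondrial DNA, where 7266 nuclear windows of that length were covered by a mean of 10.1% and at most 39.8%, but intervals of these widths at random places would already cover 52.9%, so the coverage does not test this explanation apart from the number of peaks. Occupancy of MEF2 elements by the tagged protein would need these sites in both replicates, and replicate 2's list held 0 mitochondrial peaks, but a removal of mitochondrial peaks from that list alone would give the same count. The element was present at 32% of 25 mitochondrial peaks and in 38% of their flanks (permutation p = 0.787). The explanations cannot be told apart, since how the lists were filtered is not given in the sources used here.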

How the results depend on the processing

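Tests added after the data had been seen are those on nuclear peaks alone, without peaks near mef-2, with flanks and shuffled copies together, all alternatives for elements other than the MEF2 element, and the single-replicate versions of the non-coding, signal and mef-2 results. No paired analysis was possible because the samples form 1 group. The share of strongest peaks in both replicates (45.1 to 51.6%), the share at 5' ends (43.9 to 66.9%) and the raised count at mef-2 (99.9 to 100% of windows below it) kept their direction and side of the threshold under every alternative run. The number of gene lists called was 6 to 8 and of elements 5 to 7, with changes in which ones. Of the 25 strongest peaks and the peaks of list genes, counted under each gene, 22 ranked outside the 832 strongest of replicate 2, beside those with no interval there, and 24 outside those of replicate 1. The causes of the changes that follow were not tested, and unknown depth limits all of them.

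Chromosomes past the threshold numbered 2, but 4 with the ce10 list, 5 against gene 5' ends, and 3 to 4 when a replicate was left out, and 1 without peaks near mef-2, where chromosome I lost its call (1.16 times, exact adjusted p = 0.0894). Chromosome III passed under the 5 alternatives fixed beforehand, and not without peaks near mef-2 (1.21 times, exact adjusted p = 0.0537). Chromosome II was at 0.908 to 1.09 without a replicate, reversed without replicate 1, and IV reversed to 0.882 with the 416 strongest peaks and to 0.861 to 0.936 without a replicate. Non-coding classes past the threshold rose from 1 to 3 in the short window and were 2 to 3 without a replicate, with lincRNA at 0.920 in the short window. Odds ratios changed side, without passing the threshold, for neuromuscular genes (0 with the 416 strongest), the excretory list (0 with the nearest gene only) and histones (0.510 to 1.41 without a replicate, reversed without replicate 1, and 1.21 among genes with a pooled relaxed peak). The MEF-2 list lost its call under 6 alternatives (exact or permutation adjusted p 0.0552 to 0.450) and the pan-neuronal list under 4 (0.0903 to 0.275); the other 6 lists called kept their calls under every alternative. With the 416 strongest peaks, odds ratios were 14.9 for ribosomal proteins, 5.17 for spliceosome factors, 11.3 for oxidative phosphorylation, 7.70 for the MEF-2 list, 7.74 for the pan-neuronal list and 0 for chemoreceptors. Among genes with a pooled relaxed peak they were 7.31 for the MEF-2 and 2.44 for the pan-neuronal list; the MEF-2 list was at 8.11 without replicate 1 and 8.37 without peaks near mef-2.

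The MEF2 element's difference of -1.68 points became -9.57 with TAWWWWTA (permutation p = 1e-05) and turned to 1.08 with the strict form, 1.24 with it on nuclear peaks, 3.59 against shuffled copies and 2.76 with flanks and copies together (permutation p = 0.00794). Against copies, and with flanks and copies together, WGATAR turned to 2.47 and 3.08 and TGACTCA to -1.08 and -0.152; the altered control turned to 0.431 in the second. Calls of single elements changed: CAGCTG was lost with the 416 strongest peaks (adjusted permutation p = 0.105) and WGATAR against copies (0.131) and with flanks and copies together (0.143), while TGACTCA passed against copies (0.0389) and the control on nuclear peaks (0.0497). The signal difference of peaks with the element was 16.9 with the element within 50 bp (permutation p = 0.0003), fell to 2.98 on nuclear peaks (permutation p = 0.160) and was 0.610 to 6.33 without a replicate; that at 5' ends was 1.06 with the short window and turned to -0.572 on nuclear peaks.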

Other observations

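All tests on subsets of peaks, on the strict element within them and on base composition, and the test of binding at the mef-2 gene alone, were chosen after the results had been seen; the count of intervals around mef-2 and the share of 5' end peaks with the element were planned.

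Beyond the elements fixed beforehand, a group of overlapping 6-mers marked the point sources. Of 2080 6-mers, 480 were more frequent at point sources and 434 in a flank (exact McNemar test, adjusted over all). GAGAGA was present at the point source alone in 374 peaks and in the flank alone in 47, CGTCTC in 271 against 27, ACGCAG in 222 against 19 and GACGCA in 215 against 25 (adjusted p from 5.17e-61 to 2.15e-36). Genes for SL2 RNAs, the leaders spliced onto downstream genes of operons, were among the small nuclear RNA genes with a peak: sls-2.4 (93.0), sls-2.1 (74.99), sls-2.2 (74.2) and sls-2.8 (58.7). These genes were chosen after their values were seen, and the peaks at sls-2.4, sls-2.1 and sls-2.8 also lie at protein-coding 5' ends.

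Strict MEF2 elements, CTAWWWWTAG, were more frequent than in flanks at peaks away from protein-coding 5' ends. There 11 of 374 peaks held one, 1 of them mitochondrial (2.94% against 0.134% of flanks, permutation p adjusted over 18 subset and element pairs = 0.00229), and 2 of the 457 peaks at 5' ends did (0.438% against 0.766%, adjusted permutation p = 0.655), 753 bp upstream of cua-1, a copper transporter (chromosome III, 13455890 to 13456229, signal value 56.0), and 259 bp upstream of gbas-1 (chromosome II, 2504449 to 2504788, 53.9); the difference between these sets was not tested for the strict form. The other nuclear peaks with a strict element include the mef-2 intron, a pair in introns of kin-1, the catalytic subunit of protein kinase A (chromosome I, 14922604 to 14922943 with signal value 88.6, and 14945598 to 14945716 with 75.8), and intergenic peaks 1561 bp upstream of crtc-1, a CREB coactivator (chromosome I, 2024585 to 2024924, 53.4), and 1947 bp upstream of nhr-48 (chromosome X, 15706096 to 15706435, 35.6). Apart from mef-2, these were named after their values were seen. Among the 100 strongest nuclear peaks 4 had a strict element, against 8 of the other 706 (odds ratio 3.64, Fisher's exact p = 0.0502).

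The crowding of peaks around mef-2 may come from extra copies of the region carried by the transgene, which would raise reads over the whole stretch in both replicates. The relaxed lists were called against a control, whose strain was not examined here. A control with the same copies could offset them in peak calling. Outside the gene but within 20 kb of it, 43 pooled relaxed intervals were found against a mean of 11.2, and 99.96% of 2503 nuclear windows of 40 kb held fewer. The window that did not hold fewer covers mef-2 itself, since that region was not left out of the background. Those 43 intervals lie outside the gene, so binding at the mef-2 gene alone does not account for them, but this follows from the count itself and is no separate test. The gene has room for 14.4 intervals of median width set end to end, against an excess of 35.4. Listed intervals can overlap, so that room is not a ceiling. An earlier form of the test of binding at the gene alone asked only for an element in the strongest peak, which is present. The planned count of the flanks does not favour extra copies, because the crowding itself sets it, and a cluster of bound sites would give the same. These explanations stay open, since neither read depth nor a strain without the transgene was analysed here, and the strength of the intronic peak cannot be read as occupancy alone.

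Peaks at the 5' ends of protein-coding genes, those of ribosomal and translation genes among them, could be signal at accessible promoters that does not depend on the MEF2 element. At 5' end peaks the element was found at 4.81%, -3.17 points from flanks (SE 1.42, permutation p = 0.0304), and at 6.95% of the others (Fisher's exact p = 0.232), which left the planned test undecided. Mitochondrial peaks, of which 32% of 25 held the element against 38% of their flanks, are part of the sets compared here. The 5' end share was 55.05% of all 832 peaks and 53.8% of nuclear peaks, so most mitochondrial peaks count as 5' end peaks. Mitochondrial peaks raise the share with the element in that set, so Fisher's test does not compare nuclear promoters with other nuclear sites. They were not set apart, so the values of this paragraph do not describe nuclear promoters alone. Base composition could hide the element, since GC was 7.08 points higher at these point sources than in flanks (SE 0.402); against shuffled copies its excess at 5' end peaks was 2.01 points (permutation p = 0.0379), but 1.77 in their flanks (p = 0.0524), a difference of 0.243 (SE 1.40, p = 0.864) that decides nothing. The comparison with flanks replaced tests on GC alone, which was undecided, and on shuffled copies alone, which would have favoured hiding. Away from 5' ends the same difference was 5.83 points (SE 1.54, adjusted p = 0.0003), and 5' end peaks differed from these by -5.58 points (SE 2.08, permutation p = 0.00732), so a bound element, if any, may lie mainly at the other peaks.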
